A study of Homo sapiens with 8 samples.

How the data were processed

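Reporter plasmids were transfected into HepG2 cells, a human hepatocellular carcinoma line, and K562 cells, a human leukaemia line, each in 2 independent transfections per the labels. From the cells of each transfection, DNA and RNA were purified separately, the RNA was treated with DNase and reverse transcribed, and the barcoded 3' UTR of the luciferase reporter was amplified from DNA and cDNA and sequenced as single-end reads, per the labels' protocols. The assay, CRE-seq, reads the regulatory activity of a short element as the RNA made from its plasmids relative to the DNA of the same plasmids in the same cells. All libraries of a replicate experiment were sequenced together in a single lane, per the labels' protocols.

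The deposited table holds raw read counts per barcode and library, per the file headers, with no normalization stated. Cutadapt, without a version, and the genome build hg19 are named in the submitters' processing notes, which do not say what either was used for. The aligner or counter and any filter are not given in the sources used here. Library totals were close to each other, between 9965393 and 10193122 reads, and the DNA libraries all lay between 10130870 and 10136366. Whether the depth was equalised before deposit is not given in the sources used here. Every integer at low counts occurred, so the values were treated as counts.

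The table held 12380 barcodes, 4 for each of 3095 elements, and names for each element a position, a class and whether it is a scrambled sequence. The 6 classes combine HepG2, K562 or Shared with Pol2 or NOPol2. The table does not define them. They are read here, after the series title, as the cell line of CEBPB binding and as sites with and without RNA polymerase II, and every value for HepG2-bound, K562-bound or shared sites rests on that reading. Scrambled sequences carry the name and class of the bound site they belong to. The table gives a single position per site. Element sequences, start and end positions and fragment lengths were not used here, and positions are printed as the table gives them. The gene annotation at hand is of GRCh38, a different build, so no site was assigned to a gene, exon or intron, and the planned comparisons of sequence motifs and of sites near liver or erythroid genes were not run.

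Barcodes with at least 10 reads in every DNA library were kept, 9856 in all, and elements with at least 3 such barcodes were tested. This left 8868 barcodes in 2332 elements, of which 1286 were bound sites and 1046 scrambled controls. Of these elements 1872 had 4 passing barcodes and 460 had 3. Between 97.9% and 98.7% of the reads of a library lay in the tested elements. Reads were summed over the barcodes of an element in each library. Libraries were scaled by TMM computed on the scrambled controls alone, so that a log2 RNA/DNA of 0 is the typical value of scrambled sequences. TMM factors of the HepG2 libraries were 1.164 and 1.151 for DNA and 0.763 and 0.736 for RNA, and those of the K562 libraries were 1.166 and 1.151 for DNA and 1.008 and 0.982 for RNA.

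Activity was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 8 libraries in 4 groups without a block, as RNA against DNA in each cell line and as the difference of these contrasts between cell lines. The 8 libraries share an estimate of the spread for each element. The SD of the difference between transfections over scrambled controls was 0.501 in K562 and 0.32 in HepG2. The shared spread can therefore understate that of K562 and overstate that of HepG2, and p-values of either line carry this limit. The common dispersion was 0.019 and the prior degrees of freedom 4.95. P-values were adjusted by the Benjamini-Hochberg method over all tested elements. An element was called active when its adjusted p was under 0.05, its log2 RNA/DNA was above 0, and its log2 RNA/DNA was above the 95th percentile of the tested scrambled controls in that cell line. The mirror rule with the 5th percentile defined repressed elements. The difference between cell lines was called at an adjusted p under 0.05. The SE of a difference was derived as its absolute log2 value over the square root of the F statistic. It rests on reads summed over barcodes and does not cover the spread between barcodes. By construction of the percentile, scrambled controls above it are at most 5% of all scrambled controls.

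Per transfection, log2 RNA/DNA was computed from scaled summed reads with a pseudocount of 1, and means, SDs and set comparisons use the average of the 2 transfections. Sets of elements were compared by two-sided permutation tests of the difference of means with 100000 resamples, whose smallest p is 1e-05, and by two-sided Fisher's exact tests of the share of active elements, with adjustment over the 14 class comparisons of each kind. Elements, not transfections, are the unit of these tests. Shares carry 95% exact Clopper-Pearson intervals. These intervals treat elements as the sampled unit and do not cover the spread between transfections or the error of read counts. Reads carry no molecular identifiers. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures by matplotlib 3.10.9.

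The fit was tested on simulated data drawn for all 2332 elements with 50 elements changed per size. Counts were drawn at the common dispersion of 0.019 for every element and library. Recovery was scored by adjusted p and sign, without the percentile rule. In HepG2, 28% of the elements changed by a log2 of 0.5, 100% of those changed by 1, 100% of those changed by 2 and 98% of those changed by -1 were recovered, against 0.19% of unchanged elements called. In K562 the recovered shares were 46%, 98%, 100% and 100% for the same sizes, against 0.42% called among unchanged elements. For the difference between cell lines they were 8%, 70%, 100% and 84%, against 0.38%. These shares hold for the simulated noise only. They are not rates of false calls in the data and do not rank the lines. In the data, 231 of 1046 scrambled controls in HepG2 and 103 of 1046 in K562 passed edgeR's test in either direction.

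Replicate numbers pair the libraries, because the libraries of each replicate experiment shared a lane, per the labels. Deviations from the group means over elements correlated at 0.301 between HepG2 DNA and RNA, 0.24 between K562 DNA and RNA, 0.584 between the DNA of both lines, 0.169 between their RNA, 0.373 between K562 DNA and HepG2 RNA and 0.232 between HepG2 DNA and K562 RNA.

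Alternatives fixed before the data were examined were a replicate block, TMM over all elements, scaling by total counts, DESeq2 1.42.0 with size factors from scrambled or from all elements, no minimum count, at least 50 reads per barcode, leaving out the barcode with the highest RNA/DNA of each element, the median over barcodes tested with limma 3.58.1, the 99th percentile of scrambled controls, no percentile, and leaving out each transfection in turn. The Fisher's exact tests of each class against its own scrambles, adjusted over 12, were added after seeing the data. Alternatives chosen after seeing the data were subtraction of background reads, each site against its own scrambled control, and a restriction to elements with a mean of at least 2000 reads per DNA library. Named elements were chosen by a rule fixed before the data were examined: in each cell line the 8 active sites with the highest and the 3 repressed sites with the lowest log2 RNA/DNA on the same side of 0 in both transfections, the 6 sites with the largest called difference towards each cell line with the same sign in all pairs of transfections, and the highest active scrambled control of each cell line.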

Results

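The series measured the reporter activity of genomic sites bound by CEBPB, a basic leucine zipper transcription factor, in HepG2 and K562 cells. Its title sets binding sites with promoter-distal RNA polymerase II against sites without it, and asks whether the polymerase separates active from inactive sites. Each cell line contributed 2 transfections, and each transfection a DNA library and an RNA library, 8 libraries in all. HepG2 DNA libraries held 10134385 and 10134252 reads and HepG2 RNA libraries 10193122 and 10186483. K562 DNA libraries held 10136366 and 10130870 reads and K562 RNA libraries 9989528 and 9965393. The library comprised 1730 bound sites and 1365 scrambled sequences, of which 1286 sites and 1046 scrambles had enough DNA reads to be tested. Tested sites bound in HepG2 numbered 377 with RNA polymerase II and 298 without. Those bound in K562 numbered 184 with the polymerase and 161 without, and sites bound in both lines, called shared, numbered 150 with it and 116 without.

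Activity of single elements repeated more closely in HepG2 than in K562. Across the 2332 elements, log2 RNA/DNA in the 2 HepG2 transfections correlated with a Pearson r of 0.912 and a Spearman rho of 0.73, and in the 2 K562 transfections with 0.526 and 0.45. For bound sites alone r was 0.941 in HepG2 and 0.57 in K562, and for scrambled controls 0.682 and 0.393. Elements are not independent replicates, so these values describe the transfections and carry no test. Single barcodes with 250 to 1000 reads in a pair of libraries varied, by the median over barcodes, between the K562 RNA libraries with 63.5 times the variance of counting noise, against 17.8 times for HepG2 RNA, 2.58 times for K562 DNA and 2.45 times for HepG2 DNA. Between the DNA of HepG2 and K562 the value was 3.37 in replicate 1 and 1.39 in replicate 2, the latter below that of either line's own DNA replicates. The transfections are independent per the labels, and each was counted as its own replicate.

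**Figure D1:**
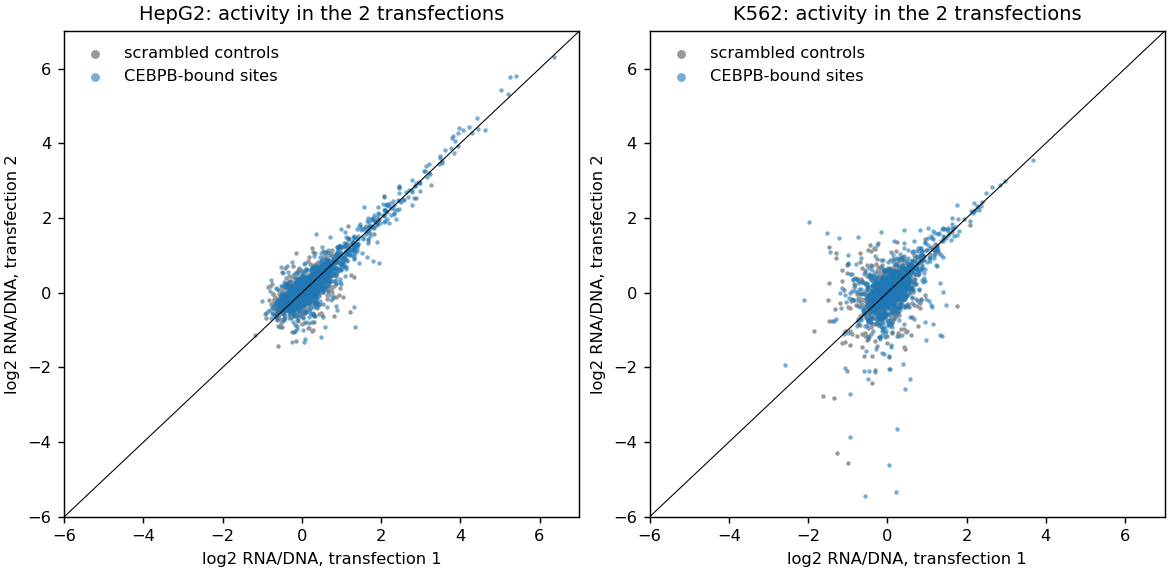
Log2 RNA/DNA of each element in transfection 1 (horizontal) and transfection 2 (vertical), in HepG2 (left) and K562 (right), for bound sites (blue) and scrambled controls (grey), with the line of equality. Points lie closer to the line in HepG2 (r = 0.912) than in K562 (r = 0.526).

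In HepG2 cells, 279 of 1286 CEBPB-bound sites were active, 21.7% (95% exact interval 19.5 to 24.1). Of the scrambled controls 48 of 1046 were active, 4.59% (3.4 to 6.04), for an odds ratio of 5.76 (Fisher's exact test, two-sided, p = 1.66e-35, adjusted 3.33e-35). Active sites had a median log2 RNA/DNA of 1.35, a 2.55-fold excess over the typical scramble, and 88 of them exceeded a log2 of 2. The mean log2 RNA/DNA was 0.42 ± 0.90 (SD over 1286 sites) for bound sites and 0.03 ± 0.37 (SD over 1046 controls) for scrambles, a difference of 0.39 (permutation p = 1e-05, the smallest the permutations can give). Against its own scrambled control a site was higher by 0.35 on the log2 scale in the mean, and 571 of 901 pairs had the site above its scramble (permutation p = 1e-05).

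The site with the highest activity in HepG2 was chr6:36634962, a shared site with RNA polymerase II, at a log2 RNA/DNA of 6.33 ± 0.03 (SD, n = 2 transfections), an 80.7-fold excess in the fit. It alone took 4.93% and 5.02% of the reads of the HepG2 RNA libraries. Next came chr10:9867491, a K562-bound site with the polymerase, at 5.62 ± 0.28 (SD, n = 2), and chr17:74547258, a HepG2-bound site with the polymerase, at 5.52 ± 0.36 (SD, n = 2). The shared sites chr10:80218871 and chr1:160983700, both with the polymerase, reached 5.27 ± 0.09 and 5.22 ± 0.28. On chromosome 6 the shared site chr6:7058754 reached 4.49 ± 0.20 and the HepG2-bound site chr6:6748911 4.42 ± 0.03, again both with the polymerase. The HepG2-bound site without polymerase chr6:89850041 reached 4.55 ± 0.17, but its 3 barcodes ranged from -0.43 to 5.22, and without the highest barcode its log2 RNA/DNA was 0.02 with an edgeR adjusted p of 0.985. Adjusted p in edgeR for these 8 sites ranged from 3.88e-12 to 1.75e-06. The most active scrambled control was that of chr6:7168564, at 2.70 ± 0.25 (SD, n = 2), with barcodes from -0.11 to 3.54. Without its highest barcode the value was 0.46 with an edgeR adjusted p of 0.582. A cutoff at the 99th percentile of scrambled controls left 155 active sites and 11 active scrambles. Without HepG2 transfection 1 there were 220 active sites and 29 active scrambles, and without HepG2 transfection 2 there were 225 and 27.

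In K562 cells, 164 of 1286 bound sites were active, 12.8% (95% exact interval 11 to 14.7), against 26 of 1046 scrambled controls, 2.49% (1.63 to 3.62). The odds ratio was 5.73 (Fisher's exact test, two-sided, p = 1.56e-21). Active sites had a median log2 RNA/DNA of 0.96, a 1.94-fold excess, and 17 exceeded a log2 of 2. Bound sites averaged 0.12 ± 0.55 (SD over 1286 sites) and scrambles -0.02 ± 0.37 (SD over 1046 controls), a difference of 0.14 (permutation p = 1e-05). A site exceeded its own scrambled control by 0.17 in the mean, in 530 of 901 pairs (permutation p = 1e-05).

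The highest K562 value, 3.61 ± 0.10 (SD, n = 2), belonged to chr16:22308680, a HepG2-bound site without polymerase, and equals a 12.2-fold excess. Its own scrambled control was the most active scramble in K562, at 1.95 ± 0.03, with all 4 barcodes between 1.75 and 2.19. Shared sites with polymerase made up much of the rest of the list: chr16:66550768 at 2.98 ± 0.0035, chr2:72110231 at 2.87 ± 0.04, chr5:5351641 at 2.41 ± 0.04 and chr20:22392623 at 2.34 ± 0.02. The HepG2-bound site with polymerase chr16:3156472 reached 2.74 ± 0.13, and the K562-bound sites with polymerase chr10:24858332 and chr10:17038369 reached 2.58 ± 0.12 and 2.30 ± 0.15. Adjusted p in edgeR for these 8 sites ranged from 1e-08 to 1.84e-05. The count of active K562 sites was 89 with the median over barcodes and 91 with the 99th percentile of scrambled controls, with 11 and 9 active scrambles.

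Few sites were repressed. In HepG2 24 of 1286 bound sites fell below the 5th percentile of scrambles and passed the test, 1.87%, against 33 of 1046 scrambles, 3.15% (Fisher's exact p = 0.0582). In K562 the counts were 16 of 1286 (1.24%) and 13 of 1046 (1.24%, Fisher's exact p = 1). The HepG2-bound site chr12:120619850, without polymerase, was low in both lines, at -1.16 ± 0.04 in HepG2 (edgeR adjusted p = 0.0053) and -1.10 ± 0.02 in K562 (edgeR adjusted p = 0.0133). The shared site without polymerase chr3:58523582 was at -0.68 ± 0.07 in HepG2 (edgeR adjusted p = 0.000452), and the K562-bound site with polymerase chr1:223976821 at -0.76 ± 0.26 (edgeR adjusted p = 0.0496, and 0.0868 with the replicate block). In K562 the K562-bound site with polymerase chr3:44481948 was at -2.27 ± 0.45 on 28 and 27 RNA reads (edgeR adjusted p = 0.0229), and the shared site without polymerase chr2:38875336 at -1.55 ± 0.68 (edgeR adjusted p = 0.0269). A fit without a transfection has fewer residual degrees of freedom and takes its shared spread from fewer libraries, and which of these moved the calls was not tested. Repressed calls were both lost and gained with a transfection left out. Of the 5 named sites 4 lost a call in this way, mostly at like values: in HepG2 chr12:120619850 was at -1.14 and -1.19 without a HepG2 transfection (edgeR adjusted p = 0.122 and 0.113) and chr1:223976821 at -0.58 and -0.95 (0.463 and 0.206), and in K562 chr3:44481948, chr2:38875336 and chr12:120619850 kept their fitted -2.34, -1.46 and -1.10 without HepG2 transfection 2, at edgeR adjusted p of 0.12, 0.0972 and 0.0704. Without K562 transfection 2, chr2:38875336 was at -1.06 (edgeR adjusted p = 0.131). Calls were also lost with all transfections in place. In K562 chr3:44481948 was at -2.36 with no minimum count (edgeR adjusted p = 0.169), -3.32 without the highest barcode (0.114) and -3.30 with the median over barcodes (limma adjusted p = 0.0712), and chr12:120619850 at -0.78 with no minimum count (edgeR adjusted p = 0.0924) and -1.33 without the highest barcode (0.0783). With the median over barcodes chr2:38875336 was at -1.39 in K562 (limma adjusted p = 0.13) and chr1:223976821 at -0.91 in HepG2 (0.121), and the latter at -0.84 without the highest barcode (edgeR adjusted p = 0.0766). Of the 5 sites, chr3:58523582 kept its call under every alternative run on it.

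The comparison named in the title set sites with RNA polymerase II against sites without it. In HepG2 cells, HepG2-bound sites with polymerase were active in 117 of 377 cases, 31.0% (95% exact interval 26.4 to 36), and those without in 44 of 298, 14.8% (10.9 to 19.3). Shared sites were active in 55 of 150 cases with polymerase, 36.7% (29.0 to 44.9), and in 23 of 116 without, 19.8% (13 to 28.3). The odds ratios were 2.6 for HepG2-bound sites (Fisher's exact test, adjusted p = 5.32e-06) and 2.34 for shared sites (adjusted p = 0.00502). Mean log2 RNA/DNA was higher with polymerase by 0.36 in HepG2-bound sites and by 0.66 in shared sites (permutation test, adjusted p = 2.8e-05 for each). Medians with and without polymerase lay closer together, at 0.23 and 0.06 in HepG2-bound sites and at 0.46 and 0.11 in shared sites. Sites bound in K562 were active in HepG2 in 27 of 184 cases with polymerase and in 13 of 161 without, 14.7% and 8.07%. Neither their share (adjusted p = 0.0819) nor their mean (difference 0.05, permutation test, adjusted p = 0.579) passed the threshold. Without the highest barcode of each element the share passed it, at an adjusted p of 0.0344. Other alternatives lowered this gap of 6.6 percentage points. It was 1.88 with no minimum count (Fisher's exact test, adjusted p = 0.498), 4.66 with the median over barcodes (0.209) and 5.64 with at least 50 reads per barcode (0.21).

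In K562 cells, K562-bound sites with polymerase were active in 41 of 184 cases, 22.3% (95% exact interval 16.5 to 29.0), and those without in 9 of 161, 5.59% (2.59 to 10.3). This gap of 16.7 percentage points was 10.9 without K562 transfection 1 and 15.8 without K562 transfection 2. It still passed at 9.47 with the median over barcodes (Fisher's exact test, adjusted p = 0.00191) and 9.87 with no minimum count (adjusted p = 6.28e-05). Shared sites were active in 49 of 150 cases with polymerase, 32.7% (25.2 to 40.8), and in 13 of 116 without, 11.2% (6.1 to 18.4). Odds ratios were 4.84 (Fisher's exact test, adjusted p = 3.08e-05) and 3.84 (adjusted p = 7.04e-05), and mean log2 RNA/DNA was higher with polymerase by 0.23 (permutation test, adjusted p = 0.00076) and 0.39 (adjusted p = 2.8e-05). Medians with and without polymerase lay closer together, at 0.12 and 0.03 in K562-bound sites and at 0.23 and 0.05 in shared sites. HepG2-bound sites were active in K562 in 29 of 377 cases with polymerase and 23 of 298 without, 7.69% and 7.72% (odds ratio 0.996, adjusted p = 1). Their means differed by 0.09 (permutation test, adjusted p = 0.00742), a difference that did not pass with at least 50 reads per barcode (0.04, adjusted p = 0.268) or in elements with at least 2000 DNA reads (0.02, adjusted p = 0.706). It was larger without the highest barcode (0.17, permutation test, adjusted p = 0.000175), with the median over barcodes (0.16, adjusted p = 0.0002) and with no minimum count (0.15, adjusted p = 0.00026). Sites with polymerase had more DNA reads than sites without: the median per library was 3740 against 2928 in HepG2-bound, 3081 against 2150 in K562-bound and 4245 against 3072 in shared sites. In elements with at least 2000 DNA reads, an alternative chosen after seeing these medians, the mean differences were 0.27 in HepG2-bound sites in HepG2 cells (adjusted p = 0.00144) and 0.22 in K562-bound sites in K562 cells (adjusted p = 0.00166).

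**Figure D2:**
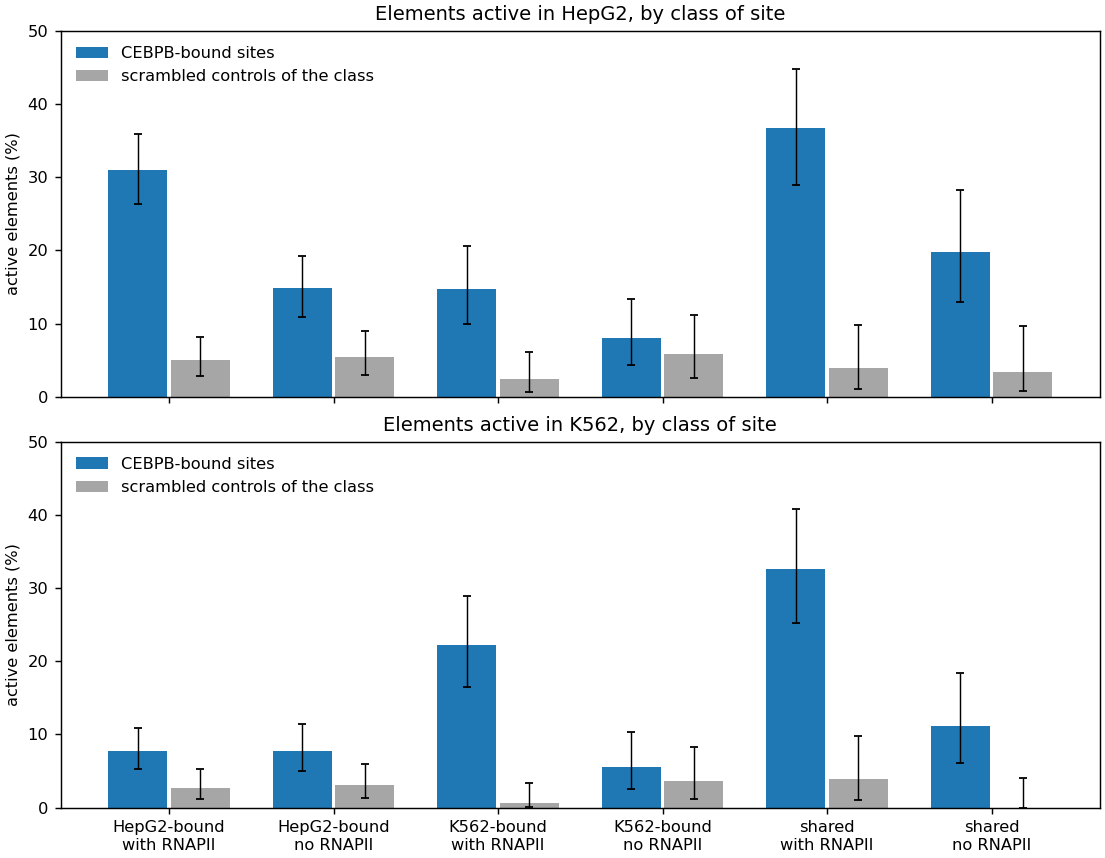
Percent of elements active in HepG2 (top) and K562 (bottom) for bound sites (blue) and scrambled controls (grey) of the 6 classes, with 95% exact intervals over elements. In HepG2 cells 31.0% of HepG2-bound sites with RNA polymerase II (RNAPII) were active and 14.8% of those without, and in K562 cells 22.3% of K562-bound sites with it and 5.59% of those without.

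Among sites with polymerase, the line of binding also separated activity. In HepG2 cells, HepG2-bound sites exceeded K562-bound sites by 0.33 in mean log2 RNA/DNA (permutation test, adjusted p = 0.000327), with an odds ratio of 2.62 for being active (Fisher's exact test, adjusted p = 5.16e-05). In K562 cells, HepG2-bound sites lay at -0.14 relative to K562-bound sites (permutation test, adjusted p = 0.00473), with an odds ratio of 0.291 (Fisher's exact test, adjusted p = 1.09e-05). That K562 mean difference was -0.11 without K562 transfection 1 (adjusted p = 0.0533) and -0.02 with no minimum count (adjusted p = 0.636). Without polymerase, HepG2-bound and K562-bound sites differed in mean by 0.03 in HepG2 (permutation test, adjusted p = 0.744) and by -0.00257 in K562 (adjusted p = 0.955). Their shares active did not pass either, at 14.8% and 8.07% in HepG2 (odds ratio 1.97, Fisher's exact test, adjusted p = 0.0543) and 7.72% and 5.59% in K562 (odds ratio 1.41, adjusted p = 0.482), though the HepG2 share passed with TMM over all elements (adjusted p = 0.0384) and without the highest barcode of each element (adjusted p = 0.0383). Other alternatives lowered that HepG2 difference of 6.69 percentage points. It was 0.87 with no minimum count (Fisher's exact test, adjusted p = 0.821), 3.19 without HepG2 transfection 1 and 2.90 without HepG2 transfection 2. In mean activity, shared sites with polymerase exceeded HepG2-bound ones by 0.33 in HepG2 (permutation test, adjusted p = 0.00343) and 0.35 in K562 (adjusted p = 2.8e-05), and K562-bound ones by 0.66 in HepG2 (adjusted p = 2.8e-05) and 0.21 in K562 (adjusted p = 0.00989). The last of these was 0.15 without K562 transfection 2 (adjusted p = 0.0602). The shares of shared and HepG2-bound sites active differed in K562 (odds ratio 5.82, Fisher's exact test, adjusted p = 7.88e-11) and did not pass in HepG2 (36.7% and 31.0%, adjusted p = 0.255). Those of shared and K562-bound sites differed in HepG2 (odds ratio 3.37, adjusted p = 1.32e-05) and did not pass in K562 (32.7% and 22.3%, adjusted p = 0.0543), though the latter passed without K562 transfection 1 (adjusted p = 0.00364), with no minimum count (0.00368), with the median over barcodes (0.0387) and without the highest barcode of each element (0.0264).

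Each class was also set against its own scrambled controls. In HepG2 cells bound sites of all 6 classes had a higher mean than their scrambles, from 0.13 in K562-bound sites without polymerase (permutation test, adjusted p = 0.0349) to 0.90 in shared sites with polymerase (adjusted p = 3e-05). In K562 cells the 3 classes with polymerase exceeded their scrambles, by 0.10 in HepG2-bound (permutation test, adjusted p = 0.000411), 0.30 in K562-bound (adjusted p = 3e-05) and 0.46 in shared sites (adjusted p = 3e-05). The means of the 3 classes without polymerase did not pass in K562, with differences of -0.01 in HepG2-bound (adjusted p = 0.834), 0.03 in K562-bound (adjusted p = 0.597) and 0.12 in shared sites (adjusted p = 0.0917). Shares active gave another picture for some of these classes, in Fisher's exact tests adjusted over 12 comparisons. Shared sites without polymerase were active in K562 in 13 of 116 cases, 11.2%, against 0 of 88 scrambles, whose exact interval reaches 4.11% (adjusted p = 0.00104), and HepG2-bound sites without polymerase in 7.72% of cases against 3.1% (adjusted p = 0.0298). K562-bound sites without polymerase did not pass in K562 (5.59% against 3.65%, adjusted p = 0.585) or in HepG2 (8.07% against 5.84%, adjusted p = 0.548). The other 5 classes in HepG2 and the 3 classes with polymerase in K562 passed, with adjusted p of at most 0.00769.

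Activity differed between the cell lines at 314 of 1286 bound sites in edgeR's test of the difference, 246 higher in HepG2 and 68 higher in K562, against 52 and 24 of 1046 scrambled controls. Scaling by total counts, which moved the median of all tested elements by -0.63 in HepG2, by -0.22 in K562 and by -0.41 in the difference, turned this split to 161 higher in HepG2 and 413 higher in K562, with 426 of 1046 scrambles called in either direction in place of 76. Numbers of sites higher in a line are therefore relative to the scrambled controls. HepG2-bound sites with polymerase were higher in HepG2 in 109 of 377 cases and higher in K562 in 6. K562-bound sites with polymerase were higher in HepG2 in 14 of 184 cases and higher in K562 in 27. The odds ratio between these classes was 4.94 for being higher in HepG2 (Fisher's exact test, adjusted p = 5.27e-09) and 0.094 for being higher in K562 (adjusted p = 6.4e-09). Among sites without polymerase, 41 of 298 HepG2-bound and 18 of 161 K562-bound sites were higher in HepG2 (adjusted p = 0.468), and 9 and 8 were higher in K562 (adjusted p = 0.411). Scrambles of the classes were called at unlike rates. Those of HepG2-bound and K562-bound sites were higher in HepG2 in 6.42% and 2.42% of cases with polymerase and in 3.49% and 10.2% without. They were higher in K562 in 3.04% and 0.606% with polymerase and in 1.55% and 2.92% without. Sites were not tested against these rates. Without HepG2 transfection 1 the total was 175 sites, 149 higher in HepG2 and 26 in K562, with 12 scrambles in either direction, and without HepG2 transfection 2 it was 183, 154 and 29, with 15 scrambles. With the median over barcodes it was 114, 100 and 14, with 6 scrambles.

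Sites active in both lines numbered 104, where independent lists would share 35.6 (odds ratio 9.38, Fisher's exact p = 3.67e-36). The count was 50 with the 99th percentile of scrambled controls, 67 with the median over barcodes and 176 with edgeR's test alone. A further 175 sites were active in HepG2 and not K562, of which 147 also passed the test of the difference, and 60 in K562 and not HepG2, of which 30 passed it. Over bound sites, mean log2 RNA/DNA in HepG2 and K562 correlated with a Pearson r of 0.396 and a Spearman rho of 0.382, across sites and without a test. Scrambled controls shared activity between lines as well, with an r of 0.371 and a rho of 0.407, and 16 were active in both lines where independent lists would share 1.19 (odds ratio 49.4, Fisher's exact p = 1.02e-16).

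The largest difference towards HepG2 was that of chr6:36634962, at 6.05 on the log2 scale (SE 0.07, edgeR adjusted p = 3.36e-11), with a K562 value of 0.29 ± 0.04 (SD, n = 2). It was followed by chr17:74547258 at 5.50 (SE 0.23), chr10:9867491 at 4.99 (SE 0.23), chr3:13512455 at 4.95 (SE 0.19), chr6:89850041 at 4.85 (SE 0.40) and chr6:64275530 at 4.36 (SE 0.18). Adjusted p in edgeR for these 6 sites was at most 2.53e-05. The difference of chr6:89850041 was -0.12 without its highest barcode. Both chr3:13512455 and chr6:64275530 are HepG2-bound sites with polymerase, and chr3:13512455 lay at 4.19 ± 0.31 in HepG2 and -0.75 ± 0.03 in K562. Towards K562 the largest difference was that of chr10:24858332, at -2.73 (SE 0.12, edgeR adjusted p = 5.08e-07), a K562-bound site with polymerase at -0.14 ± 0.11 in HepG2. The shared sites with polymerase chr1:235012237, chr6:3410120 and chr1:182269290 differed by -1.99 (SE 0.14), -1.80 (SE 0.18) and -1.47 (SE 0.10). The K562-bound sites with polymerase chr10:17038369 and chr14:91891886 differed by -1.54 (SE 0.24) and -1.49 (SE 0.42). For chr14:91891886 the edgeR adjusted p was 0.0406, and it was 0.154 without HepG2 transfection 2, 0.112 without K562 transfection 1 and 0.115 without K562 transfection 2. Its K562 barcodes ranged from -1.67 to 2.13, and the difference was -0.76 without the highest barcode (edgeR adjusted p = 0.485) and -1.11 with the median over barcodes (limma adjusted p = 0.261).

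**Figure D3:**
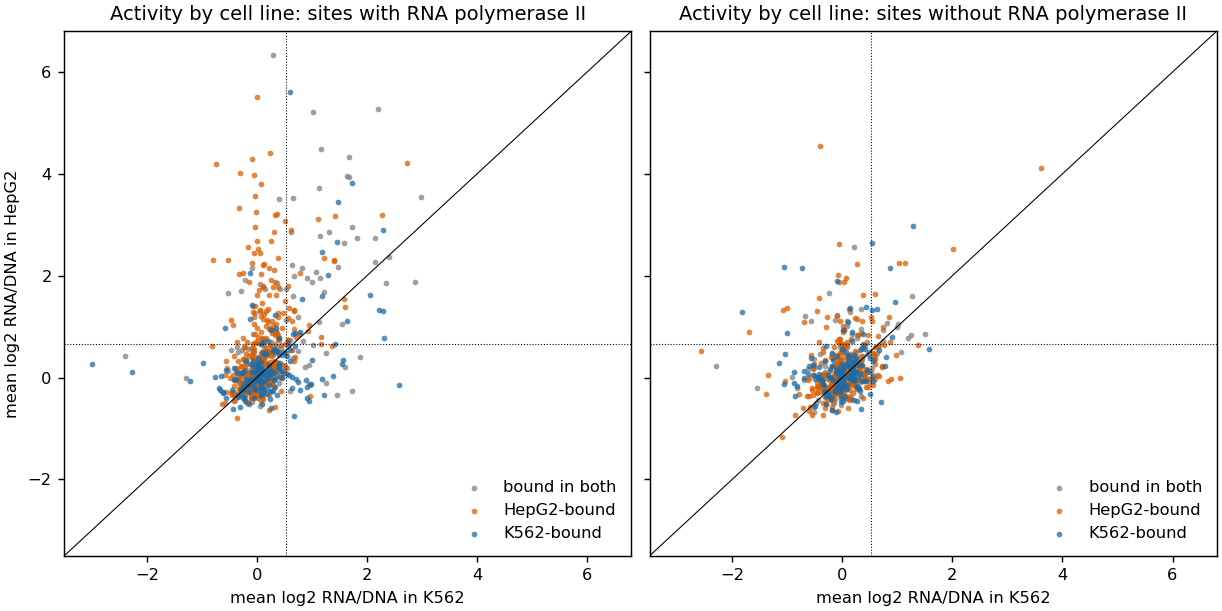
Mean log2 RNA/DNA of bound sites over 2 transfections in K562 (horizontal) and HepG2 (vertical), for sites with (left) and without (right) RNA polymerase II, coloured by the line of CEBPB binding. Solid lines mark equality and dotted lines the 95th percentile of scrambled controls, 0.66 in HepG2 and 0.52 in K562.

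**Figure D4:**
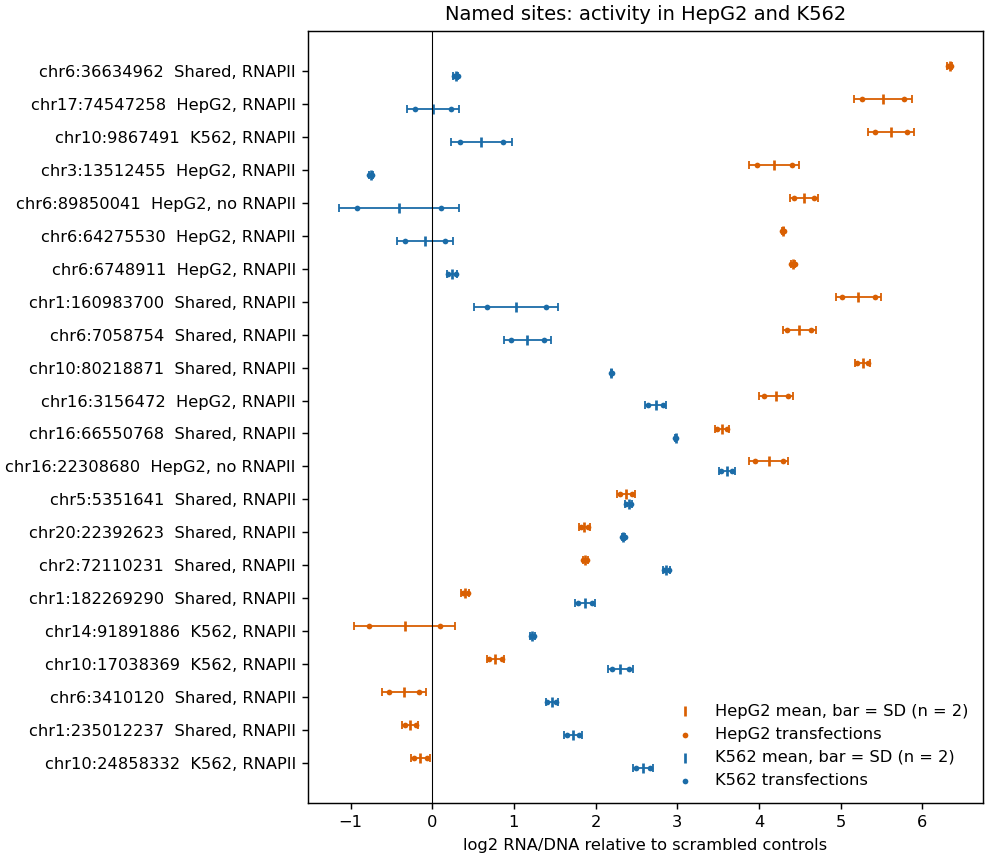
Log2 RNA/DNA of the named active sites and of the sites with the largest differences between lines, in HepG2 (orange) and K562 (blue). Dots are the 2 transfections, ticks their mean and bars the SD, and sites are ordered by the difference between lines, from -2.73 at chr10:24858332 to 6.05 at chr6:36634962.

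The difference between sites with and without polymerase was itself set against the cell line. In HepG2-bound sites the difference of means with and without polymerase was 0.36 in HepG2 cells and 0.09 in K562 cells (difference 0.26, permutation test of the difference, adjusted p = 0.00018). In K562-bound sites it was 0.05 in HepG2 and 0.23 in K562 (difference -0.18, adjusted p = 0.0299), and in shared sites 0.66 and 0.39 (difference 0.27, adjusted p = 0.0256). This test was not among those planned. It permutes sites and does not cover the spread between transfections. The K562 value of shared sites was 0.49 without K562 transfection 1 and 0.30 without K562 transfection 2. Bound sites exceeded scrambles by 0.39 in HepG2 and 0.14 in K562 (difference 0.25, adjusted p = 4e-05). These are differences of means, and the SD over bound sites was 0.55 in K562 and 0.90 in HepG2. For shares active, the odds ratio of bound sites against scrambles was 5.76 in HepG2 and 5.73 in K562. In shared sites the gap in shares with polymerase was 16.8 percentage points in HepG2 and 21.5 in K562. In HepG2-bound sites it was 16.3 and -0.03, and in K562-bound sites 6.6 and 16.7, the same way as the means. Shares were not tested between lines.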

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

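The tests on near-empty barcodes were written after those barcodes had been noticed; the ratio of means, the barcodes at 0 and the number of barcodes a single base away were chosen after the counts had been seen.

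The difference in mean log2 RNA/DNA between sites with and without RNA polymerase II differed between cell lines by 0.264 in HepG2-bound sites, by -0.176 in K562-bound sites and by 0.267 in shared sites, as HepG2 minus K562 in a permutation test of the difference. Bound sites minus scrambles differed by 0.247 between the lines in the same test. These are differences of means. For shares active, the odds ratios of bound sites against scrambles were alike, 5.76 in HepG2 and 5.73 in K562.

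Activity of named sites differed between lines in edgeR's test of the difference, given here as log2 HepG2 minus K562. Shared sites with polymerase differed by 6.05 at chr6:36634962, 3.08 at chr10:80218871, 4.17 at chr1:160983700, 3.31 at chr6:7058754, 0.57 at chr16:66550768, -0.99 at chr2:72110231, -0.48 at chr20:22392623, -1.99 at chr1:235012237, -1.80 at chr6:3410120 and -1.47 at chr1:182269290. HepG2-bound sites with polymerase differed by 5.50 at chr17:74547258, 4.17 at chr6:6748911, 1.47 at chr16:3156472, 4.95 at chr3:13512455 and 4.36 at chr6:64275530. K562-bound sites with polymerase differed by 4.99 at chr10:9867491, -1.45 at chr1:223976821, -2.73 at chr10:24858332, -1.54 at chr10:17038369 and -1.49 at chr14:91891886, the last of which was -0.76 without its highest barcode. HepG2-bound sites without polymerase differed by 4.85 at chr6:89850041, a value carried by a single barcode, and by 0.52 at chr16:22308680. The scrambled controls of chr6:7168564 and chr16:22308680 differed by 1.48 and -0.76.

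Barcodes that were nearly empty in both replicate 2 DNA libraries, 2412 with fewer than 10 reads, still held reads in the replicate 1 libraries. Their median was 16 reads in HepG2 DNA, 14 in HepG2 RNA, 21 in K562 DNA and 10 in K562 RNA of replicate 1, against 2, 1, 1 and 1 in replicate 2. Plasmids at low copy in the transfected pool are argued against as the whole source, not by the ratio of means in DNA (14.2 in K562 and 7.69 in HepG2, replicate 1 over replicate 2), which restates how these barcodes were chosen, but by the barcodes of the whole library at 0: 616 in K562 DNA and 290 in HepG2 DNA of replicate 2, against 0 and 3 in replicate 1, at like library totals. Sequencing errors in abundant barcodes one base away are argued against by the count of near-empty barcodes with such a neighbour, 0, which also left the planned correlation without values. Errors from barcodes 2 bases away cannot be told apart from other sources: reads correlated with those of such neighbours at a Spearman rho of 0.242 in K562 and 0.255 in HepG2 (permutation p = 1e-05, the smallest possible), between the bounds set for either reading, and a property of the lane that the libraries of a replicate shared was not tested, nor was any biological explanation.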

How the results depend on the processing

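Restriction to deeper elements, background subtraction and pairing with own scrambles were chosen after seeing the data. Counts are of bound sites, and causes were not tested. Bound sites exceeded scrambles in both lines under every alternative run. With the replicate block, where DNA and RNA of a transfection share a term, 281 sites were active in HepG2, 167 in K562, 24 and 13 were repressed and 316 differed between lines; apart from chr1:223976821 it changed no other named call. Of 496 values for 36 named results under alternatives, 463 kept direction and call, 32 lost the call and 1 reversed: the difference at chr6:89850041, -0.12 without its highest barcode. Some named results could not be tested with at least 50 reads per barcode and are left out of that tally. They are those of chr6:89850041, chr12:120619850, chr1:223976821, chr3:44481948, chr14:91891886 and the scrambled control of chr6:7168564. Elements with few DNA reads repeated less well in both lines. A minimum of 5 barcodes gave no value because elements have 4.

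Total counts gave 40 repressed sites in HepG2, 29 in K562 and 574 differences. DESeq2 gave 25 repressed in K562 with scrambled and 27 with all-element size factors. No minimum count gave 3 repressed in K562 and reproducibility r of 0.721 in HepG2 and 0.352 in K562, and at least 50 reads gave r of 0.939 and 0.659. Without the highest barcode 11 were repressed in HepG2 and 3 in K562, with 16 and 5 repressed scrambles. The median over barcodes gave 5 and 3 repressed, 89 active in K562 and 114 differences. The 99th percentile gave 155 and 91 active and 5 and 3 repressed, and edgeR alone 76 and 40 repressed. Active scrambles in HepG2 numbered 22 with total counts, 29 with no minimum count, 20 with the median and 136 with edgeR alone, and repressed scrambles 51, 23, 2 and 95. Leaving out each transfection gave 220 to 290 active in HepG2 and 121 to 145 in K562, 6 to 29 repressed in HepG2 and 5 to 29 in K562, and 175 to 326 differences.

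HepG2 shares active, in percentage points, passed the threshold for HepG2-bound minus K562-bound sites without polymerase with TMM over all elements (7.31) and without the highest barcode (6.93), and for K562-bound sites with minus without polymerase without the highest barcode (7.84). In the same order, these 2 differences fell to 0.87 and 1.88 with no minimum count. Without a HepG2 transfection the first ranged from 2.90 to 3.19 and the second from 4.58 to 5.20. In K562 the share of HepG2-bound sites with minus without polymerase, near 0, turned positive with TMM over all elements (0.310), no minimum (1.21), the median (1.56), without the highest barcode (0.911), with background subtracted (0.645) and without a K562 transfection (1.46 to 1.61). The K562 mean of HepG2-bound minus K562-bound sites without polymerase, also near 0, turned positive with no minimum (0.0629), at least 50 reads (0.0165), the median (0.0476), without the highest barcode (0.101) and in deep elements (0.0167), and ranged from -0.0216 to 0.0164 without a K562 transfection, their share from -0.657 to 1.98. With polymerase that mean weakened to -0.0238 with no minimum and ranged from -0.159 to -0.114 without a K562 transfection. Shared minus K562-bound share with polymerase passed in K562 with no minimum (11.4), the median (9.38) and without the highest barcode (12.01), and also without K562 transfection 1 (14.1), and ranged from 6.44 to 14.1 without a K562 transfection, the mean from 0.154 to 0.271. The K562 mean of HepG2-bound sites with minus without polymerase lost its call at 0.0421 with at least 50 reads and 0.0164 in deep elements. It rose to 0.171 without the highest barcode, 0.159 with the median and 0.148 with no minimum.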

Other observations

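The comparison of sites with the line that did not bind them, the count of scrambles active in both lines, the comparison of lines at like DNA reads and the regional counts were chosen after the results had been seen.

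Some sites were active in the line in which CEBPB binding was not assigned. K562-bound sites were active in HepG2 in 40 of 345 cases (11.6%), against 12 of 302 of their scrambles (3.97%), an odds ratio of 3.17 (Fisher's exact test, adjusted p = 0.000412). By class, those with polymerase passed against their scrambles (14.7% against 2.42%, Fisher's exact test, adjusted p = 0.000101). Those without it did not (8.07% against 5.84%, adjusted p = 0.548). HepG2-bound sites were active in K562 in 52 of 675 cases (7.7%), against 16 of 554 scrambles (2.89%), an odds ratio of 2.81 (adjusted p = 0.000412). Of the 40 sites 24 were also active in K562 and 16 were not, and of the 52 sites 34 were also active in HepG2 and 18 were not. On chromosome 6, all 3 tested sites between positions 6748911 and 7151008 were active in HepG2 and 2 of them in K562, and 4 of 6 between 901057 and 1389881 were active in HepG2 and 1 in K562. No chance level was computed for these regions.

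The 2 K562 transfections agreed less than the 2 HepG2 transfections. A smaller range of activity over the same noise is argued against as the whole source. The SD of the difference between transfections over scrambled controls was 1.57 times as large in K562 as in HepG2. A smaller range as a part of the source is not excluded. The SD of mean log2 RNA/DNA over bound sites was 0.55 in K562 and 0.90 in HepG2. Background reads of equal size per barcode are argued against as the whole source. After subtraction of the median background of each library from every barcode, r in K562 was 0.471, against 0.526 before. The subtraction cannot remove background that differs between barcodes, so such background stays open. Elements with few DNA reads agreed less in both lines, with r of 0.864 above the median of DNA reads and 0.353 below it in K562, and 0.967 and 0.861 in HepG2. As the sole source of the gap between lines they are argued against, since below the median, at like DNA reads (medians 1256 in K562 and 1260 in HepG2), the SD between transfections was 1.84 times as large in K562 (bootstrap 95% interval 1.65 to 2.04); above it the ratio was 1.21 (1.14 to 1.3), so the gap was smaller among elements with more DNA reads. A difference in biology between the lines stays open and untested.

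Some scrambled controls were active, with a median log2 RNA/DNA of 0.88 over 48 in HepG2 and 0.76 over 26 in K562. The cutoff is a percentile of these same controls, and up to 5% of them lie above it by construction. That some were called active is therefore no finding of its own. Noise that differs between transfections, independently in each line, is argued against as the whole source, because 16 were active in both lines, 13.4 times the 1.19 of independent lists. Noise that the libraries of a replicate share across lines is not argued against by this count. Replicate deviations correlated between the lines at 0.584 in DNA and 0.169 in RNA. A single barcode carrying the sum may account for part: without the highest barcode 39.6% of active scrambles stayed active in HepG2 and 57.7% in K562, against 82.8% and 82.3% of active bound sites, and of the 16 active in both lines 6 stayed active in both. Active scrambles also lay closer to the cutoffs, 0.66 in HepG2 and 0.52 in K562, than active bound sites, with medians of 1.35 and 0.96. The contrast therefore cannot separate a single barcode from distance to the cutoff. Properties shared with the matched site cannot be told apart from other sources, as scrambles of active sites were active at an odds ratio of 0.959 in HepG2 and 2.1 in K562 (Fisher's exact p = 1 and 0.181), on 8 and 5 pairs with both active. No biological explanation was tested.

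A hypothesis that a site and its scramble move together was not borne out, with a Spearman rho of 0.0367 in HepG2 and 0.0555 in K562 over 901 pairs (permutation p = 0.273 and 0.0952). A hypothesis that sites within 10 kb of each other act alike stays open: over 79 pairs the mean absolute difference was 0.811 against 0.974 for random pairs of the same classes in HepG2 (one-sided permutation p = 0.0761) and 0.509 against 0.532 in K562 (p = 0.365), and the bound set for rejecting it, a p of 0.05 or more, was too weak to exclude anything. A hypothesis that the GC content of the barcode moves RNA/DNA stays open as well, with a Spearman rho over 3965 scrambled barcodes of -0.156 in HepG2 transfection 1 (permutation p = 1e-05), -0.0428 in HepG2 transfection 2, -0.0407 in K562 transfection 1 and -0.00164 in K562 transfection 2.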
